A study of Phaseolus vulgaris with 6 samples.

How the data were processed

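RNA sequencing of apical stems of Phaseolus vulgaris compared the wild type A18 with the mutant nts, with 3 samples of each. Reads were handled with cutadapt 1.9 and FastQC, per the submitters' processing notes. The aligner, the counting tool and its strand setting, the genome build and the annotation version are not given in the sources used here. Coordinates are therefore printed as the table gives them, and gene descriptions, GO terms and KEGG pathways come from the same table. The RefSeq gene table for this species shares no identifiers with it and was not used.

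The deposited table gives raw counts per gene, per the file headers, as whole numbers whose totals differ between samples. Low counts pile up on multiples of 4: among counts from 1 to 39, between 29.8% and 33.0% in each library were divisible by 4, although 23.1% of the whole numbers in that range are, and in A18 replicate 1, 218 genes had exactly 4 counts against 77 with 3 and 53 with 5. How the authors arrived at these counts is not stated, so a count need not equal 1 sequenced fragment, and totals and floors hold in the unit of the table. The deposited FPKM values were made by the authors, per the file headers and the design text, and genes with 0 counts stand there at a floor of 0.0001, which was set to 0 for means. Of the 27012 genes, 3673 had 0 counts in all 6 libraries. All per-sample columns were used.

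Total counts per sample were 62695701, 40728394 and 53379710 for A18 and 61113606, 58560842 and 46361548 for nts. At these depths the spread between replicates, not counting error, sets the precision for all but the lowest genes: the common biological coefficient of variation was 0.487. Floors cover counting error only, and a fold against a genotype with 0 counts was computed against 3 counts per library and given as a lower bound. Counts of libraries of a genotype differed by more than sampling noise (chi-square per gene from 35.0 to 116), so no library was treated as a duplicate.

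Differences were tested on the deposited counts with edgeR 4.0.16 (quasi-likelihood F test with robust estimation, TMM factors from 0.957 to 1.06, filterByExpr at its defaults) in R 4.3.3, with genotype as the only term. Genes were called at a Benjamini-Hochberg adjusted p under 0.05, and log2 changes are nts minus A18. The test gives no standard error of its own. Those printed with edgeR log2 changes are the size of the change divided by the square root of the F statistic, and so restate the test. After the filter 21126 genes were tested. The same fit gave the count at the thresholds of the design text, a log2 change of at least 2 in size and an unadjusted p of at most 0.05. The authors' own test and aligned reads were not used here.

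Gene lists were defined by words in the gene descriptions, 32 in all, and 31 had at least 5 tested members. They were tested with camera of limma 3.58.1 on log2 CPM (prior count 3) with a preset correlation of 0.01 between genes, and again with an estimated correlation, with adjustment over the 31 lists. With the estimated correlation 0 lists were called and 0 had an unadjusted p under 0.05. In fry, which asks whether a list's genes move on balance in a single direction, 0 were called and 8 had an unadjusted p under 0.05. In its mixed form, which asks for change in either direction, 24 were called. Members were also counted at a p adjusted over the list alone. Terms of 10 to 500 tested genes were tested with one-sided Fisher exact tests, adjusted over both directions. Neighbouring calls were counted in windows of 20 tested genes against 10000 permutations (1000 in the alternatives). A one-sided Fisher exact test of each list among genes past the design text's thresholds (62 tests, adjusted together) was added after the data were seen.

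The tests, the gene lists, the first alternatives and the rule for naming genes were set before the data were examined. The rule took, among called genes with a mean FPKM of at least 5 in the higher genotype, full separation of the genotypes and an informative description, the 8 with the largest rise and the 8 with the largest fall, up to 3 called members of each list, up to 2 undescribed genes in each direction, and genes of a window that passed its test. As 1 list member alone was called over all genes, the other list members named as examples were chosen after their values were seen.

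The procedure was tested on simulated data for this comparison, with 21126 genes and the dispersions of these samples. It recovered 0 of 50 genes changed 2-fold, 20 of 50 changed 4-fold, 31 of 50 changed 8-fold and 43 of 50 changed 16-fold, and called 8 of 20926 unchanged genes. A list of 60 genes shifted by a log2 change of 1 was called, and 0 of 99 unshifted lists were. The simulated genes were drawn independently, so this does not cover lists whose genes vary together. In the real lists the estimated correlation between genes ran from -0.031 to 0.834. Alternatives were DESeq2 1.42.0, other scaling factors, limma on log2(FPKM + 1) and log2(FPKM + 0.1) over genes with an FPKM of at least 1, no filter and a stricter filter on low counts, the replicate number as a block, and leaving out each library in turn. Added after the data were seen were leaving out A18 replicate 2 and nts replicate 3 together, voom with quality weights, a surrogate variable from sva 3.50.0, counts divided by 4, and edgeR without robust estimation. Figures were drawn with matplotlib 3.10.9.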

Results

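Gene expression was measured by RNA sequencing in the apical stems of common bean (Phaseolus vulgaris), in the wild type A18 and the mutant nts. Plants were sampled at the first flowering stage, once the stem tips of the mutant had come to differ from those of the wild type. Each genotype had 3 samples. The deposited table lists 27012 gene models on 11 chromosomes with a read count and an FPKM value, a fragment level scaled to transcript length and sequencing depth, for every sample. Total counts were 62695701, 40728394 and 53379710 in A18 replicates 1, 2 and 3. They were 61113606, 58560842 and 46361548 in nts replicates 1, 2 and 3. Between 5125 and 5726 genes had 0 counts in a library, and the 10 most abundant genes took between 3.22% and 4.71% of the counts. Nothing in the labels says whether the samples of a genotype came from separate plants, so the p-values measure only the spread between these samples.

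The genotypes separated on the first principal component of log2 CPM (counts scaled to library size), which held 54.8% of the variance. A18 replicates 1 and 3 stood at -112 and -116 and nts replicates 1 and 2 at 122 and 102, whereas A18 replicate 2 at -36.1 and nts replicate 3 at 40.3 lay between these groups. Across genes, which are not independent replicates, A18 replicates 1 and 3 correlated with r = 0.959 and nts replicates 1 and 2 with r = 0.961. A18 replicate 2 correlated with A18 replicates 1 and 3 at 0.887 and 0.894, and with nts replicate 3 at 0.901. The correlation of nts replicate 3 with nts replicates 1 and 2 was 0.907 and 0.896. Secondary wall markers did not follow this order on the A18 side. Their mean log2 CPM was 5.98 in A18 replicate 2, against 5.59 and 6.04 in replicates 1 and 3, while nts replicate 3 stood at 2.91 against 0.48 and 0.65 in nts replicates 1 and 2.

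**Figure D1:**
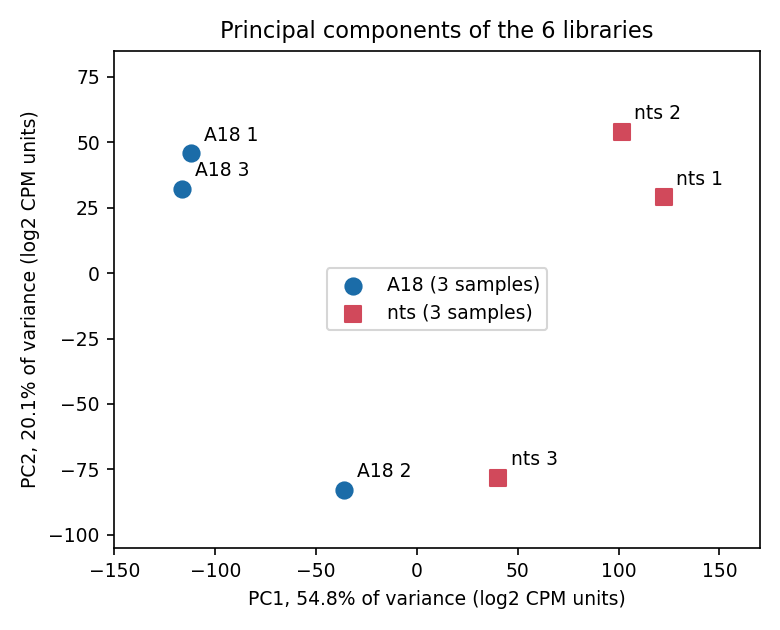
First and second principal components of log2 CPM, with 1 point per library, circles for A18 and squares for nts. The axes hold 54.8% and 20.1% of the variance, and A18 replicate 2 and nts replicate 3 lie between the other libraries of the 2 genotypes on the first axis, at -36.1 and 40.3.

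The comparison of nts with A18 asks which transcripts differ in the stem apex of the mutant. The genes that were lower included a FASCICLIN-like protein and MYB85, both of kinds known from the secondary walls of fibres and xylem. Phvul.011G076900 (chromosome 11, 7091970 to 7092845), a FASCICLIN-like arabinogalactan-protein 11 of the family found in secondary walls of stems, fell from 230.5 ± 124 to 0.334 ± 0.177 FPKM (mean ± SD, n = 3 per genotype; edgeR log2 change -9.31 ± 0.71 SE, adjusted p = 0.0319). Phvul.003G214300 (chromosome 3, 44101442 to 44103212), MYB85, a transcription factor of the secondary wall programme in Arabidopsis, fell from 21.9 ± 10.6 to 0.731 ± 0.175 FPKM (edgeR log2 change -4.77 ± 0.48, adjusted p = 0.0397, n = 3). Phvul.001G154300 (chromosome 1, 40486986 to 40492951), a NIMA-related kinase 4, dropped from 81.6 ± 11.3 to 1.40 ± 0.838 FPKM (edgeR log2 change -5.79 ± 0.48, adjusted p = 0.0319, n = 3). On the higher side, Phvul.009G110400 (chromosome 9, 17066795 to 17068011), GATA transcription factor 12, rose from 1.05 ± 0.372 to 13.3 ± 2.81 FPKM (edgeR log2 change 3.73 ± 0.35, adjusted p = 0.0378, n = 3).

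In all, 20 of 21126 tested genes changed at an adjusted p under 0.05, 13 of them lower and 7 higher in nts. The lower genes also included a leucine-rich repeat family protein (Phvul.011G115300, log2 change -6.35 ± 0.63), a PLC-like phosphodiesterase (Phvul.003G048300, -5.39 ± 0.35), a leucine-rich repeat protein kinase (Phvul.006G071600, -3.41 ± 0.32) and a transmembrane amino acid transporter (Phvul.002G113000, -2.49 ± 0.25). The phosphodiesterase had 7.88 ± 1.08 FPKM in A18 and 0.170 ± 0.0367 in nts. Phvul.009G017800 and Phvul.001G020800, which carry no description, fell from 225 ± 72.7 to 7.92 ± 2.21 and from 40.6 ± 13.7 to 2.80 ± 0.401 FPKM.

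The higher genes further held a P-loop nucleoside triphosphate hydrolase (Phvul.005G005000, log2 change 4.04 ± 0.38) and a 2-oxoglutarate and iron-dependent oxygenase (Phvul.005G058800, 3.18 ± 0.30), a superfamily that includes enzymes of hormone metabolism. A remorin (Phvul.003G243700) rose by 2.27 ± 0.21, a pentatricopeptide repeat protein (Phvul.003G194000) by 2.01 ± 0.16 and a matrix metalloproteinase (Phvul.002G076700) by 1.73 ± 0.17 on the log2 scale. The metalloproteinase was the most abundant of the 7, with 29.1 ± 2.27 FPKM in A18 and 91.4 ± 6.63 in nts. Outside the rule for naming genes, and chosen after their values were seen, were a DUF579 protein (Phvul.001G262300, -2.94 ± 0.30), an unknown seed protein like 1 (Phvul.009G024700, -2.78 ± 0.28), a DUF688 protein (Phvul.002G239200, -2.50 ± 0.20), an undescribed gene (Phvul.006G023700, -2.11 ± 0.18) and a DUF1191 protein (Phvul.006G081000, 2.36 ± 0.24). Some DUF579 proteins act in methylation of the secondary wall polymer xylan, and the description does not say whether Phvul.001G262300 is one of them.

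**Figure D2:**
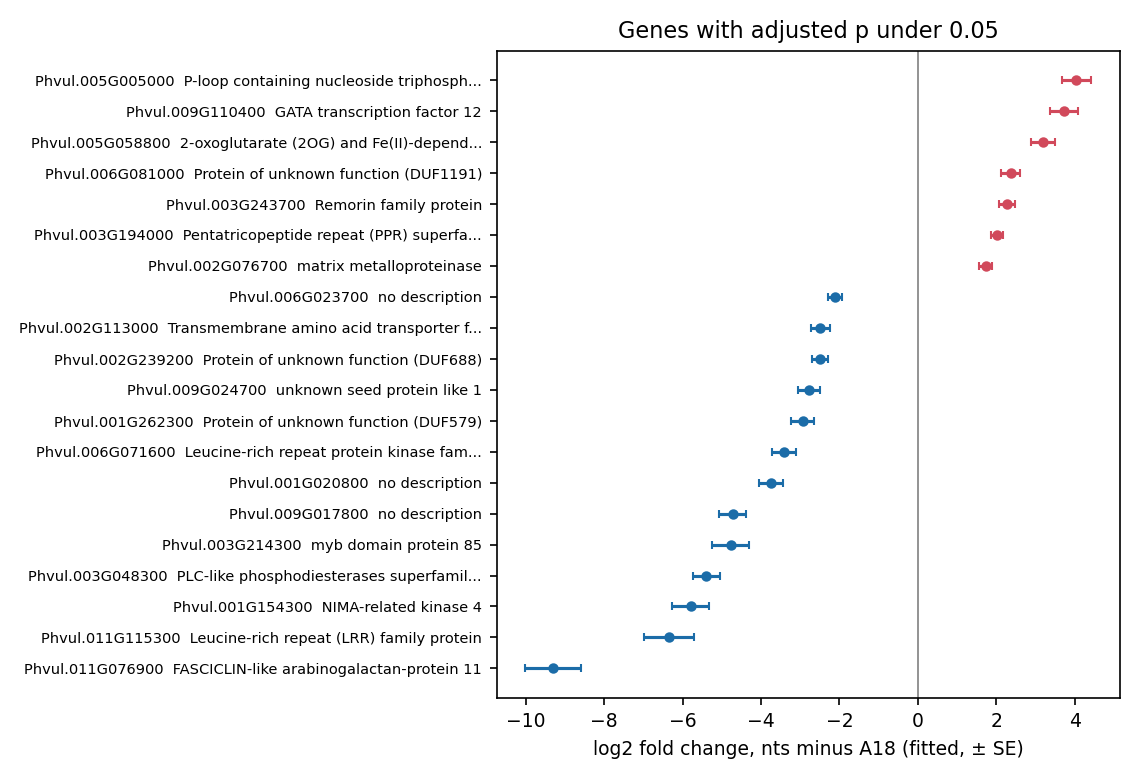
Fitted log2 fold change, nts minus A18, of the 20 genes with an adjusted p under 0.05, with bars of 1 standard error and the file's gene description. The 13 lower genes range from -9.31 to -2.11 and the 7 higher genes from 1.73 to 4.04.

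All 20 genes had every library of a genotype above every library of the other. So did 24.4% of the tested genes, against 10% by chance, and 3796 genes had an unadjusted p under 0.05. The edgeR count was 0 without A18 replicate 1, A18 replicate 3 or nts replicate 1 and 1 without nts replicate 2, but 945 without A18 replicate 2, 964 without nts replicate 3, 4267 without both of these and 2395 with DESeq2.

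At the thresholds of the study's design text, a log2 change of at least 2 in size and an unadjusted p of at most 0.05, nts had 436 genes higher and 711 lower, 1147 in all. Of the gene lists described in the following paragraphs, secondary wall, lignin, peroxidase, meristem and seed storage genes were over-represented on the lower side, and auxin response, gibberellin, expansin and seed storage genes on the higher side. The light signalling list was over-represented there too, but 10 of its 11 higher genes were GDSL-like lipases. These Fisher tests treat genes as independent, and with an estimated correlation camera called 0 lists (lowest adjusted p = 0.690). Of the 1147 genes, 19 also had an adjusted p under 0.05, 6 higher and 13 lower. Of the 1147 genes, 1019 had an adjusted p under 0.05 under DESeq2, 955 with quality weights, 885 without A18 replicate 2 and nts replicate 3, and 159 with a surrogate variable. As the 1147 were chosen on these same libraries, such counts say nothing about their stability. The total at the study's thresholds was 1768 without A18 replicate 2, with 927 higher and 841 lower, and 1733 without nts replicate 3, with 520 higher and 1213 lower.

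Among 126 tested genes of cellulose synthesis and the secondary wall, 27 fell and 10 rose adjusted over the list alone, and 1 fell over all genes tested. At the study's thresholds 31 were lower and 3 higher, more lower genes than the background gives (one-sided Fisher exact test, adjusted p = 4.87e-17). Of the 27 that fell 17 were FASCICLIN-like arabinogalactan-proteins, and the 91 members outside that family had 14 lower and 2 higher at the study's thresholds (one-sided Fisher exact test, unadjusted p = 2.05e-06 for lower). As a whole these 91 were not lower, with 57 above 0, a median log2 change of 0.24 and 8 rising against 10 falling adjusted over the list alone (camera direction up, unadjusted p = 0.383). Among the former, Phvul.011G076000 (protein 12) had 296 ± 209 FPKM in A18 and 0.123 ± 0.126 in nts, and Phvul.011G077100 (protein 11) 460 ± 331 and 0.320 ± 0.398 (list-alone adjusted p = 0.00472 for each, edgeR, n = 3). Galacturonosyltransferase-like 2 (Phvul.002G026000) fell from 125 ± 19.9 to 17.4 ± 7.92 FPKM, a log2 change of -2.78 ± 0.42 (edgeR, list-alone adjusted p = 0.00472). Cellulose synthase A4 (Phvul.007G190300), a subunit of the secondary wall cellulose synthase, had 18.3 ± 14.6 and 0.0695 ± 0.0686 FPKM, with an adjusted p of 0.0809 over all genes tested. Of the other cellulose synthase A4 genes, Phvul.009G242700 had 515 ± 119 and 52.9 ± 77.7 FPKM (edgeR log2 change -3.17 ± 1.24, adjusted p = 0.252) and Phvul.002G188600 1.16 ± 1.43 and 1.35 ± 0.874 (edgeR log2 change 0.21 ± 1.14, adjusted p = 0.947). The list as a whole was not called by camera (direction down, adjusted p = 0.235; 0.7998 with an estimated correlation), its median log2 change being 0.11 and its mean -1.70, or -1.55 with genes at 0 counts in a genotype set to their bound. Camera called it lower on DESeq2 statistics (median 0.10, adjusted p = 0.000224). The FASCICLIN-like genes 11 and 12 include a run of 14 neighbouring copies on chromosome 11, from 6921838 to 7145916, all 14 of them with negative log2 changes, and the split of reads among such copies is uncertain.

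Lignin and phenylpropanoid genes were lower as a group. Of 60 tested, 10 fell and 2 rose adjusted over the list alone, and none over all genes tested. The median log2 change was -0.81 (camera adjusted p = 0.00671 with the preset correlation, adjusted p = 0.782 with an estimated correlation). A laccase (Phvul.008G107100), of the oxidases that polymerise lignin, had 168 ± 148 FPKM in A18 and 0.176 ± 0.132 in nts (edgeR, list-alone adjusted p = 0.0171). The 4-coumarate:CoA ligase 2 genes, which activate the precursors of lignin, fell in parallel: Phvul.003G147000 from 293 ± 89.8 to 57.6 ± 30.6 FPKM and Phvul.005G184500 from 71.6 ± 18.6 to 16.7 ± 10.2 (edgeR, list-alone adjusted p = 0.0193 and 0.0254). Cinnamyl alcohol dehydrogenase 9 (Phvul.002G268500) rose from 56.6 ± 8.92 to 118 ± 23.9 FPKM (edgeR, list-alone adjusted p = 0.0192). At the study's thresholds 15 were lower and 2 higher (Fisher exact test, adjusted p = 1.87e-08 for lower). Of all listed members, tested or not, 40 are disease-resistance-responsive dirigent-like proteins. Of the 22 tested dirigent-like genes 2 were lower at those thresholds, and of the 38 other members 13 were lower and 2 higher. One-sided Fisher exact tests for lower gave an unadjusted p of 0.168 and 1.59e-10, in a split made after the values were seen. The median log2 changes were -0.56 and -1.82. The camera call was lost without A18 replicate 2 (median -0.22, adjusted p = 0.0858), and the median was -1.49 without nts replicate 3.

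Class III peroxidases, some of which oxidise lignin precursors in the wall, went both ways. Of 50 tested, 7 fell and 2 rose adjusted over the list alone, and 11 were lower against 3 higher at the study's thresholds (Fisher exact test, adjusted p = 8.13e-06 for lower). Phvul.006G075900 fell from 28.4 ± 7.20 to 5.80 ± 2.59 FPKM and Phvul.006G129700 rose from 17.3 ± 1.68 to 62.9 ± 19.0 (edgeR, list-alone adjusted p = 0.0197 and 0.00997). The median log2 change was -0.37, and camera did not call the list (adjusted p = 0.164; 0.690 with an estimated correlation). It did so without A18 replicate 3 (adjusted p = 0.00670) and without nts replicate 1 (0.0494).

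Auxin response genes were over-represented among the genes that were higher, mainly through SAUR-like genes, a family of small transcripts induced early by auxin. Of 117 tested, 28 rose and 11 fell adjusted over the list alone, 29 were higher and 5 lower at the study's thresholds (Fisher exact test, adjusted p = 1.50e-21 for higher). The median log2 change was 0.52 (camera adjusted p = 0.000282 with the preset correlation, adjusted p = 0.690 with an estimated correlation). SAUR-like genes made up 66 of those tested, 22 of the 28 that rose and 8 of the 11 that fell. Of them 26 were higher at the study's thresholds, against 3 of the 51 other members (one-sided Fisher exact test, unadjusted p = 5.60e-27 and 0.0881). Phvul.011G131300 went from 7.13 ± 3.10 to 81.9 ± 32.8 FPKM, Phvul.011G131600 from 10.8 ± 4.89 to 94.0 ± 42.2 and Phvul.009G015900 from 4.30 ± 3.28 to 76.9 ± 38.2 (edgeR, list-alone adjusted p = 0.0104, 0.0119 and 0.0129). Auxin response factor 4 (Phvul.005G136900), a transcription factor of auxin signalling, fell from 82.1 ± 32.1 to 20.1 ± 2.63 FPKM (edgeR, list-alone adjusted p = 0.0104). The list's median was 0.80 without A18 replicate 2.

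Gibberellin genes had a median log2 change of 1.69 over 25 tested members, of which 5 rose and 1 fell adjusted over the list alone (camera adjusted p = 0.00671, adjusted p = 0.690 with an estimated correlation). The members that rose included gibberellin-regulated family proteins, small cysteine-rich proteins of which Phvul.009G181500 went from 19.6 ± 13.8 to 311 ± 230 FPKM and Phvul.007G248900 from 0.0996 ± 0.173 to 20.004 ± 5.70 (edgeR, list-alone adjusted p = 0.0366 and 0.0105). Gibberellin 2-oxidases, which inactivate gibberellins, went opposite ways. Gibberellin 2-oxidase 6 (Phvul.001G215000) rose from 0.298 ± 0.413 to 12.3 ± 7.30 FPKM (edgeR, list-alone adjusted p = 0.0384). Gibberellin 2-oxidase 8 (Phvul.007G052000) had 8.39 ± 8.12 FPKM in A18 and 0 counts in all 3 nts libraries. It was at least 142-fold lower against a floor of 3 counts per library, a bound that holds in the unit of the table. At the study's thresholds 8 members were higher, 5 of them gibberellin-regulated proteins, and 1 lower (Fisher exact test, adjusted p = 3.80e-07 for higher). The 17 other members had a median of 0.94 (camera with the preset correlation, unadjusted p = 0.0867). The camera call was lost without A18 replicate 2 (adjusted p = 0.0522), without nts replicate 3 (median 1.08, adjusted p = 0.0992) and without both (median 1.21, adjusted p = 0.0883).

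**Figure D3:**
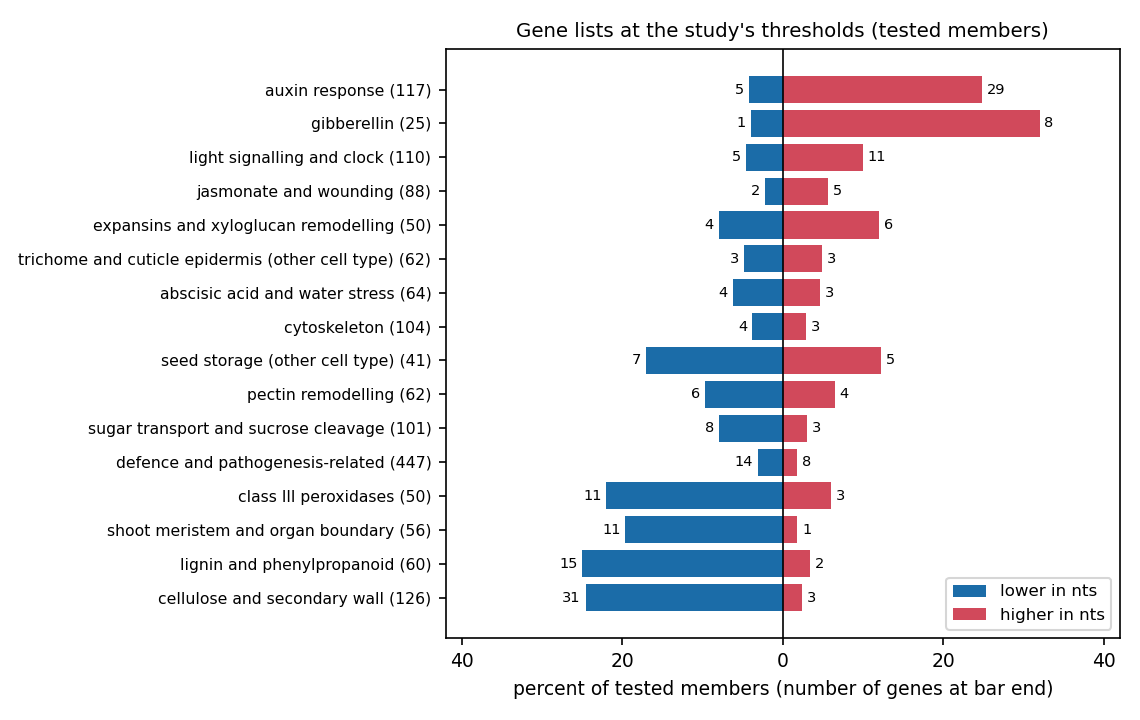
Share of each list's tested members past the study's thresholds, in percent, lower in nts to the left and higher to the right, for lists with at least 6 such genes in both directions together; the number of genes stands at the bar end. Cellulose and secondary wall (31 lower, 3 higher) and lignin (15 lower, 2 higher) lie at the bottom, and auxin response (29 higher, 5 lower) and gibberellin (8 higher, 1 lower) at the top.

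Expansins and xyloglucan enzymes, which loosen the primary wall of growing cells, were higher as a group, with 37 of 50 tested above 0 and a median log2 change of 0.46 (camera adjusted p = 0.00779, adjusted p = 0.782 with an estimated correlation). Adjusted over the list alone 3 rose and 1 fell. Expansin B3 (Phvul.005G104600) rose from 26.2 ± 16.8 to 118 ± 41.4 FPKM and xyloglucan endotransglucosylase/hydrolase 8 (Phvul.007G052800) from 15.8 ± 10.5 to 80.5 ± 19.2, while endotransglucosylase/hydrolase 32 (Phvul.011G085200) fell from 195 ± 146 to 5.10 ± 4.90 (edgeR, list-alone adjusted p = 0.0485 for each). At the study's thresholds 6 were higher and 4 lower (Fisher exact test, adjusted p = 0.00379 for higher). The camera call was lost without A18 replicate 3 (median 0.27, adjusted p = 0.0700), without nts replicate 3 (median 0.26, adjusted p = 0.0707) and on DESeq2 statistics (adjusted p = 0.0754). The median was 1.35 without A18 replicate 2, and 0.26 to 1.46 over all settings.

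Shoot meristem and organ boundary genes were lower as a group at the settings used. The list was drawn by family words such as KNAT, LOB domain and CLAVATA, so a member need not act in the meristem. Of 56 tested, 9 fell and 1 rose adjusted over the list alone, 11 were lower and 1 higher at the study's thresholds (Fisher exact test, adjusted p = 2.25e-05 for lower). The median log2 change was -0.44 (camera adjusted p = 0.00779, adjusted p = 0.690 with an estimated correlation). KNAT6 (Phvul.003G062500), a homeobox gene of the meristem and its boundaries, fell from 15.3 ± 2.79 to 5.97 ± 1.55 FPKM, and KNAT3 (Phvul.009G090500) from 70.0 ± 10.9 to 38.5 ± 2.14 (edgeR, list-alone adjusted p = 0.0360 for each). LOB domain-containing protein 41 (Phvul.008G005500) fell from 21.7 ± 7.19 to 3.97 ± 0.925 FPKM and the peptide gene CLE12 (Phvul.007G101800) from 9.16 ± 6.55 to 0.694 ± 0.332 (edgeR, list-alone adjusted p = 0.0348 and 0.0360). Growth-regulating factor 5 (Phvul.009G228000), a promoter of cell proliferation in leaves, rose from 1.26 ± 0.490 to 4.58 ± 1.83 FPKM (edgeR, list-alone adjusted p = 0.0360). The camera call was lost with the stricter filter on low counts (median -0.21, adjusted p = 0.0691) and with counts divided by 4 (median -0.21, adjusted p = 0.0638). The median was -0.67 without A18 replicate 3, -0.73 without nts replicate 2 and -1.02 without nts replicate 3.

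Ethylene genes had a median log2 change of -1.06, with 12 of 14 tested below 0 (camera adjusted p = 0.0165, adjusted p = 0.690 with an estimated correlation). Ethylene response factor 1 (Phvul.007G193700) had 1.42 ± 0.722 FPKM in A18 and 0 counts in nts and was the member that fell adjusted over the list alone (edgeR, adjusted p = 0.0310). ACC synthase 10 (Phvul.002G152200) had 15.95 ± 4.60 FPKM in A18 and 5.50 ± 3.30 in nts, and an ethylene insensitive 3 family gene (Phvul.008G207000) 142 ± 45.0 and 55.8 ± 30.1, without passing that test. At the study's thresholds 3 were lower and 0 higher (Fisher exact test, adjusted p = 0.0588). The camera call was lost with the stricter filter on low counts (median -0.12, adjusted p = 0.235) and with counts divided by 4 (median -0.12, adjusted p = 0.237). It was also lost on log2(FPKM + 1) and log2(FPKM + 0.1) (medians -0.22 and -0.23, adjusted p = 0.241 and 0.282), and the median was -1.94 without nts replicate 3.

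Photosynthesis genes, which mark leaf and green cortex tissue, were higher as a group. Of 94 tested, 69 were above 0 and 25 below, with a median log2 change of 0.41 (camera adjusted p = 3.32e-06, adjusted p = 0.690 with an estimated correlation). Of these 14 rose and 0 fell adjusted over the list alone, none passing the study's thresholds. The 14 that rose were light-harvesting and photosystem II genes, 10 of them copies of the light-harvesting gene LHCB1. The 80 members other than LHCB1 had 55 above and 25 below 0 and a median of 0.31 (camera with the preset correlation, unadjusted p = 0.000258). Light-harvesting complex of photosystem II 5 (Phvul.004G128200) rose from 413 ± 34.8 to 827 ± 146 FPKM, light-harvesting chlorophyll B-binding protein 3 (Phvul.005G085800) from 239 ± 46.6 to 508 ± 110.3 and photosystem II subunit X (Phvul.009G228600) from 95.6 ± 21.4 to 187 ± 27.1 (edgeR, list-alone adjusted p = 0.0331, 0.0405 and 0.0184). The list holds a run of 6 neighbouring copies of LHCB1 on chromosome 4, from 23117284 to 23387454, all 6 with positive log2 changes, and the split of reads among them is uncertain. The 3 small chain genes of Rubisco, the enzyme that fixes carbon dioxide, had log2 changes of -0.52, -0.58 and -0.57 and a phosphoribulokinase one of -0.35, without passing the test. Cell cycle genes were above 0 in 59 of 76 cases, with a median of 0.36 (camera adjusted p = 0.0183, adjusted p = 0.7998 with an estimated correlation), and 0 passed adjusted over the list alone. A cyclin-dependent kinase inhibitor (Phvul.003G244700) had 16.4 ± 6.87 FPKM in A18 and 60.05 ± 11.9 in nts, and cyclin D2;1 (Phvul.009G143200) 5.44 ± 1.57 and 12.4 ± 2.73. All 9 tested genes of the cytosolic ribosomal protein list were above 0 (median 0.52; camera adjusted p = 0.0485, adjusted p = 0.7998 with an estimated correlation), and the 9 tested genes of the histone list had a median of 0.70 (adjusted p = 0.0536; 0.782 with an estimated correlation). Drawn by words in the descriptions, these lists hold 9 and 12 genes and need not cover their families. The cell cycle call was lost without A18 replicate 2 (adjusted p = 0.165), nts replicate 1 (0.132) or nts replicate 2 (median 0.16, adjusted p = 0.268), and the median was 0.58 without nts replicate 3. The ribosomal call was lost without any of A18 replicates 1, 2 and 3 (0.0968, 0.117 and 0.0725) or nts replicates 1 and 2 (0.132 and 0.268). It was also lost with upper quartile factors (0.0535), the stricter filter (0.0691), counts divided by 4 (0.0638) and a surrogate variable (0.0516). The histone list was called without A18 replicate 1 (0.0300), A18 replicate 3 (0.0418) or nts replicate 3 (0.00661). It was called too on DESeq2 statistics (0.0388), with no filter on low counts (0.0436) and with a surrogate variable (0.0160).

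In the list of light signalling and clock genes, in which 87 of 141 listed members are GDSL-like lipases, 9 of 110 tested rose and 3 fell adjusted over the list alone (camera adjusted p = 0.294, adjusted p = 0.782 with an estimated correlation; Fisher exact test at the study's thresholds, adjusted p = 0.000154 for higher). Of the 61 tested lipases 10 were higher at those thresholds, and of the 49 other members 1 (one-sided Fisher exact test, unadjusted p = 4.45e-07 and 0.640, a split made after the values were seen). Phytochrome interacting factor 3 (Phvul.001G218800), a transcription factor of light and growth responses, rose from 25.9 ± 1.41 to 77.0 ± 10.9 FPKM (edgeR, list-alone adjusted p = 0.00899). Of 23 auxin transport and synthesis genes 3 rose and 2 fell adjusted over the list alone (camera adjusted p = 0.559). An auxin efflux carrier (Phvul.003G032500) rose from 16.1 ± 5.30 to 62.6 ± 20.4 FPKM, and YUCCA 3 (Phvul.007G238900), of the family that makes auxin from indole-3-pyruvate, had 0 counts in A18 and 0.569 ± 0.422 FPKM in nts (edgeR, list-alone adjusted p = 0.0295 for each).

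Unlike the photosynthesis list, the 4 lists drawn up for other cell types were not called by camera. Phloem and sieve element genes had a median log2 change of -0.17 over 15 tested (adjusted p = 0.568), pollen, anther and flower genes 0.38 over 26 (adjusted p = 0.124; 4 rose and 1 fell over the list alone), and trichome and cuticle genes 0.21 over 62 (adjusted p = 0.383). Seed storage genes, of which 101 of 105 listed are 2S albumin superfamily members that include lipid-transfer proteins, had a median of -0.02 over 41 tested, with 4 rising and 7 falling over the list alone (camera adjusted p = 0.718). At the study's thresholds 5 were higher and 7 lower (Fisher exact test, adjusted p = 0.00922 and 0.00305; camera adjusted p = 0.875 with an estimated correlation).

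Marker sets, drawn up after the lower secondary wall genes had been seen, moved by different amounts. The mean log2 CPM of 48 secondary wall synthesis markers was lower by a log2 difference of -4.52 ± 0.80 (SE over libraries), with 44 of them lower. Their median fitted log2 change was -3.34. The set includes the run of 14 neighbouring FASCICLIN-like copies, whose split of reads is uncertain, and the mean would be smaller in size without them. FASCICLIN-like genes outside that run and genes described as DUF579 proteins are in the set too. The size of its change is therefore not that of secondary wall genes at large. The 13 genes taken as markers of tracheary elements, the water-conducting cells of the xylem, differed by -1.30 ± 0.56, with a median fitted log2 change of -0.69. They were drawn by words in the descriptions, so a member need not be specific to these cells or promote their formation. The 5 cellulose synthases of the primary wall differed by 0.61 ± 0.36, the 19 phloem markers by -0.29 ± 0.28 and the 94 photosynthesis genes by 0.36 ± 0.13. These means were described and not tested between the genotypes.

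**Figure D4:**
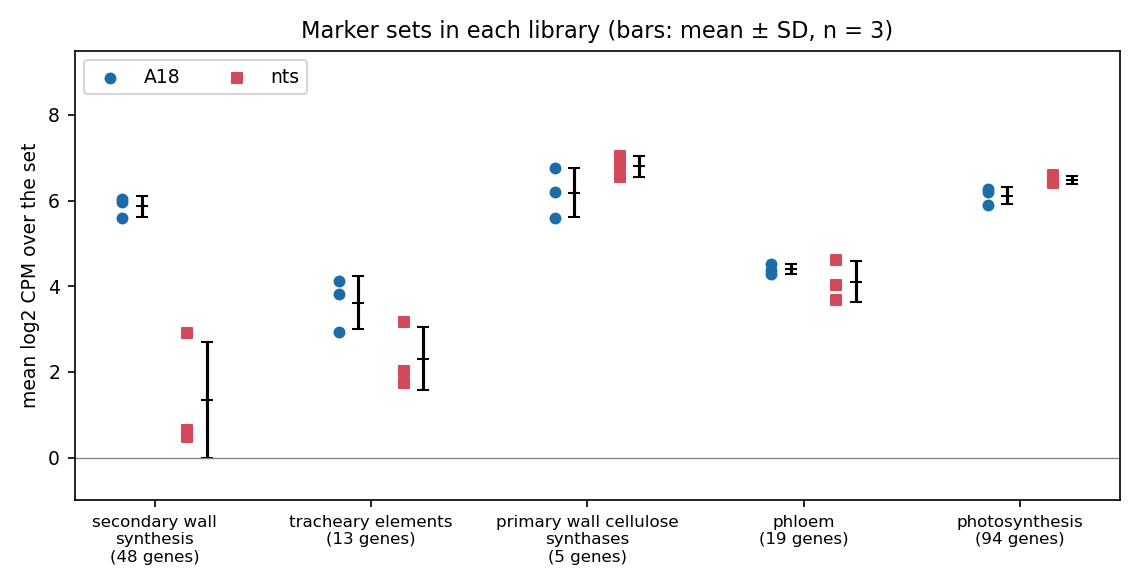
Mean log2 CPM of 5 marker sets in each library, circles for A18 and squares for nts, with black bars for the mean ± SD of 3 libraries beside the points. The secondary wall set lies between 5.59 and 6.04 in A18 and between 0.48 and 2.91 in nts.

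The remaining lists were not called by camera either. Sugar transport and sucrose cleavage genes had 2 rising and 8 falling of 101 over the list alone (adjusted p = 0.867). Of its 162 listed members 84 are invertase or pectin methylesterase inhibitors, which gave 1 of the 2 and 4 of the 8. Of the other lists, pectin remodelling had 2 and 4 of 62 (adjusted p = 0.383) and flowering and floral organ identity 4 and 1 of 50 (adjusted p = 0.358). Jasmonate and wounding genes had 3 and 0 of 88 (adjusted p = 0.867), abscisic acid and water stress 0 and 2 of 64 (adjusted p = 0.867), cytoskeleton genes, of which 7 of 117 listed are ethylene-forming enzymes, 1 and 1 of 104 (adjusted p = 0.545), and defence and pathogenesis-related genes 1 and 0 of 447 (adjusted p = 0.901). No member passed over the list alone among flavonoid and isoflavonoid (27 tested, median log2 change -0.55, adjusted p = 0.248), glutathione transferase and redox (157, -0.08, 0.559), cytokinin (19, 0.02, 0.559), brassinosteroid (25, 0.02, 0.718), heat shock and folding (155, -0.04, 0.855), or gravity response and starch genes (42, -0.01, 0.867). Flavonoid genes were called lower without A18 replicate 1 (adjusted p = 0.0409) and without nts replicate 2 (0.0127), and with the replicate number as a block (0.0358). Pectin genes were called higher on log2(FPKM + 1) and log2(FPKM + 0.1) (adjusted p = 0.0470 and 0.0477). The strigolactone list had 2 listed genes, 0 of which had enough counts to be tested.

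Among the genes past the study's thresholds, annotated terms of the wall and of hormones were over-represented. Plant-type secondary cell wall biogenesis held 31 of its 60 tested genes on the lower side (one-sided Fisher exact test, adjusted p = 6.47e-27), xylan biosynthesis 9 of 18 (5.42e-07), lignin biosynthesis 16 of 70 (3.12e-07) and the phenylpropanoid pathway 32 of 276 (6.02e-07). General terms passed on both sides: cell wall with 30 of 346 genes lower (0.000309) and 23 higher (0.000138), and cell wall organization with 25 of 176 lower (3.12e-07) and 13 higher (0.00662). On the higher side also stood response to auxin with 30 of 188 genes (1.45e-15), response to cold with 22 of 236 (7.61e-07), gibberellic acid signalling with 6 of 49 (0.0351) and water channel activity with 5 of 36 (0.0460). In all 43 terms passed, and among the 20 genes called over all genes tested 0 did, with 20 of 2542 tests at an unadjusted p under 0.05.

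Genes called with a log2 change of at least 2 in size did not gather on chromosomes: any 20 neighbouring tested genes held at most 1 of the 19 (one-sided permutation test, p = 1). In most settings with more calls the FASCICLIN-like genes of chromosome 11 formed a cluster, of 12 called genes in 20 without A18 replicate 2 or without nts replicate 3, and of 15 under DESeq2, 14 of them FASCICLIN-like, between positions 6921838 and 7145916 (p = 0.001 for each, the smallest that 1000 permutations can give). With no filter on low counts and 37 genes called, the densest 20 genes held 2 calls, on chromosome 2, 0 of them FASCICLIN-like (permutation p = 0.555).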

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

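The alternatives that leave out A18 replicate 2 and nts replicate 3 together, weight libraries in voom, fit a surrogate variable, divide counts by 4 or drop robust estimation were chosen after the data were seen, as were the test of lists among genes past the study's thresholds and the division of lists by gene family. The 20 called genes had the same sign in all 19 alternatives fitted to them, which says nothing about stability, since they were chosen on these libraries and each had every library of a genotype above every library of the other. Which genes passed depended on the setting, and the cause was not tested. At the same depth and number of samples, simulated data recovered 0 of 50 genes changed 2-fold with the spread of these samples, and 22 of 50 with dispersions divided by 4. At 4-, 8- and 16-fold, 20, 31 and 43 of 50 were recovered with the spread of these samples. On the same 6 libraries DESeq2 called 2395 genes, so the count depends on the test as well as on the spread.

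Against 20 called genes (7 higher, 13 lower), DESeq2 gave 2395 (1031 and 1364), limma on log2(FPKM + 1) 478 (199 and 279) and on log2(FPKM + 0.1) 401 (162 and 239). No filter on low counts gave 37 (18 and 19), a surrogate variable 270 (144 and 126) and counts divided by 4 gave 171 (82 and 89). Leaving out A18 replicate 2 and nts replicate 3 gave 4267 (2069 and 2198), and voom with quality weights 5087 (2420 and 2667). Other scaling factors, the stricter filter and non-robust estimation gave between 20 and 22.

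Leaving out each library in turn gave from 0 to 964 called genes, 0 to 574 higher and 0 to 594 lower. The count was 0 without A18 replicate 1, A18 replicate 3 or nts replicate 1, where edgeR had 2717, 2483 and 2418 genes at an unadjusted p under 0.05, and 1 without nts replicate 2; DESeq2 was run on all 6 libraries alone. It was 945 without A18 replicate 2 and 964 without nts replicate 3.

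Against 1147 genes past the study's thresholds (436 higher, 711 lower), log2(FPKM + 1) gave 747 (289 and 458), the 2 libraries left out 2477 (1041 and 1436) and quality weights 2333 (955 and 1378). Leaving out each library gave 1013 to 1768 genes, 369 to 927 higher and 640 to 1213 lower, the highest totals being 1768 without A18 replicate 2 and 1733 without nts replicate 3.

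The 9 lists called by camera became 0 with an estimated correlation and 0 in fry, and 5 to 10 with each library left out, 5 without A18 replicate 2. The 10 enriched lists and directions at the study's thresholds became 21 with 2 libraries left out, 19 with quality weights and 9 to 20 with each library left out, 20 without A18 replicate 2. Enriched terms numbered 0 among called genes and 43 among genes past the study's thresholds.

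The most called genes in 20 neighbours, 1 in the main test, was 15 under DESeq2, 12 and 13 on log2(FPKM + 1) and log2(FPKM + 0.1), 15 with 2 libraries left out, 13 with quality weights, 6 with a surrogate variable and 10 with counts divided by 4, each with p = 0.001, the smallest that 1000 permutations can give. It ran from 0 to 12 with each library left out, 12 without A18 replicate 2 or without nts replicate 3.

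With the replicate number as a block, 0 genes were called (0 higher, 0 lower; edgeR, 3192 at an unadjusted p under 0.05), against 1149 past the study's thresholds and 10 lists by camera. Samples that share a number did not deviate together: the pairing correlations of their deviations from the group means were -0.016, -0.130 and 0.039 for numbers 1, 2 and 3. Of the 6 samples, nts replicate 3 alone correlated best with the sample of its own number.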

Other observations

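The correlations of differences between libraries and the test of a wrong label were chosen only after the values of A18 replicate 2 and nts replicate 3 were seen. Detected in a single genotype were 26 genes, which had at least 1 CPM in all 3 libraries of a genotype and 0 counts in all 3 of the other, 20 of them in A18 and 6 in nts. With the 0 counts asked of the other libraries alone, the 6 became 33 without A18 replicate 2 and 10 without A18 replicate 1 or 3, and the 20 became 51, 28 and 36 without nts replicate 3, 1 and 2. Among those found in A18 were a nucleotide-sugar transporter (Phvul.010G007700, 32.8 ± 33.1 FPKM, at least 486-fold lower in nts), FASCICLIN-like arabinogalactan-protein 11 (Phvul.011G077200, 23.6 ± 16.2, at least 329-fold), the cytochrome P450 CYP81D3 (Phvul.009G244200, 9.53 ± 6.04, at least 234-fold) and cationic amino acid transporter 6 (Phvul.003G225700, 8.03 ± 4.32, at least 229-fold). Those found in nts included a leucine-rich repeat protein kinase (Phvul.005G163800, 8.74 ± 6.82 FPKM, at least 354-fold higher), an HXXXD-type acyl-transferase (Phvul.006G098800, 5.67 ± 1.92, at least 123-fold) and MYB26 (Phvul.005G157600, 6.62 ± 2.09, at least 80.7-fold), a regulator of wall thickening in Arabidopsis anthers. These examples were chosen after their values were seen. None of the 26 genes was called, with adjusted p from 0.0541 to 0.109 (edgeR). The bounds divide a mean over 3 libraries by 3 counts, and the nucleotide-sugar transporter ranged from 4.22 to 67.1 CPM in A18. Since low counts pile up on multiples of 4, 3 counts may be less than 1 fragment, and the bounds would then be too high.

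The real split of the 6 samples gave 20 called genes against at most 0 in the 9 others, 1147 genes past the study's thresholds against at most 463, and 26 genes in a single genotype against at most 3. In each case 1 of 10 splits gave as many, and 10 splits cannot give a share under 0.05. The split with 463 genes set A18 replicates 1 and 3 and nts replicate 3 against the rest.

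The 26 genes found in a single genotype were weighed against segments of chromosome that differ between the lines. They lay on 10 of the 11 chromosomes, and 20 neighbouring listed genes held at most 2 of them (permutation p = 0.365), which goes against a gathering of many such genes in a segment. That window, on chromosome 5 from 38513036 to 38665026, held MYB26 (Phvul.005G157600), found in nts, and Phvul.005G157900, found in A18. Scattered sequence differences that keep reads from being counted, and regulation by the genotype, remain open and were not tested.

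A18 replicate 2 lay towards nts and nts replicate 3 towards A18. Lower depth is argued against: with all libraries thinned to 40728394 counts, A18 replicate 2 still correlated with A18 replicate 1 at 0.890, against 0.961 for A18 replicate 3, and nts replicate 3 with nts replicate 1 at 0.910, against 0.963 for nts replicate 2. On a wholly wrong label the 48 secondary wall markers give no independent test, since they were drawn up after lower values in nts had been seen under these labels. Their mean log2 CPM was 5.98 in A18 replicate 2, above the 0.48 to 2.91 of the nts libraries. In nts replicate 3 it was 2.91, below the 5.59 to 6.04 of A18. Admixed RNA remains possible for A18 replicate 2. There 33 genes with 0 counts in A18 replicates 1 and 3 reached a median of 19.6% of the nts mean, although 6 were at 0. On the same measure A18 replicates 1 and 3 had medians of 0% over 10 genes each. For nts replicate 3 the median was 1.32% over 51 genes with an upper quartile of 8.14%. This cannot be told apart from none because the bound of 5% lies between these values. The medians of nts replicates 1 and 2 were 0%, with upper quartiles of 0.33% and 6.71%. Variation of the stems along the axis that separates the genotypes, a difference in developmental stage included, stays open as an untested hypothesis: changes within a genotype correlated across genes with changes between genotypes in other libraries (r = 0.382 for A18 replicate 2, 0.284 for nts replicate 3; 0.341 to 0.471 and 0.284 to 0.479 over 6 choices of libraries each), but this restates where the libraries lie, and admixed RNA would give it too.

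The lower secondary wall genes of nts were set against changes in the makeup of the stem. The 48 secondary wall markers differed by -4.52 in mean log2 CPM. The 19 phloem markers differed by -0.292 and the 5 primary wall cellulose synthases by 0.612, above -2.26, the bound set at a division of that change by 2. The bound rests on markers drawn up after lower secondary wall genes had been seen, so lying above it excludes little. It would also be smaller in size without the FASCICLIN-like genes, which make up much of the secondary wall set. The primary wall genes did not fall, which goes against a general fall of cellulose synthase transcripts. As far as the phloem markers mark phloem, their small mean change goes against an equal loss of all vascular tissue as the whole cause. Most of them are phloem protein 2 genes, and 11 of the 19 were lower. The sucrose-proton symporter 2 genes had fitted log2 changes of -0.88, -0.82 and -1.34, but 2.44 for Phvul.004G085100, which raises the mean. A smaller loss of phloem is thus not excluded. The phloem markers do not bear on the share of xylem or fibres. Fewer differentiating tracheary elements were not told apart from a change within cells. Their 13 markers differed by -1.30, above the bound of -2.26. The standard error of 0.686 for that distance treated both marker sets as independent. Both were measured in the same libraries, so this standard error does not decide the question in either direction. The mean of -1.30 leans on a xylem serine peptidase 1 gene (Phvul.010G088400, fitted log2 change -7.80). The median fitted log2 change was -0.69, with 9 of the 13 lower. Delayed or reduced wall thickening in the fibres and xylem of the nts stem apex stays open as a hypothesis that the counts did not test, as does sampling of A18 and nts stems at different distances from the tip; stem sections at matched positions would bear on both.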
